A study of Mus musculus with 24 samples.

How the data were processed

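Total RNA of 4 mouse multiple myeloma lines was amplified, labelled with biotin and hybridised to Illumina mouse bead arrays with 1 colour, per the labels' protocols. The deposited table of the series holds, per the file headers, 1 average signal intensity per probe and array for 45281 probes and 24 arrays, on a linear scale from 31.94 to 38749.43, with no normalization. It was used for all main values. A table of the authors' processed values also exists, with every array at the same median intensity of 64.4. The deposited values there are intensity values too. Their sorted values differ between arrays by at most 1.51% and from the mean of the sorted unnormalized signals by at most 0.0682%, as after quantile normalization without background subtraction, and the tool that made them is not given in the sources used here. It served as an alternative, on the log2 scale. The table used holds no detection p-values and no control probes. The planned background step, which needs them, was therefore replaced.

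Samples were grouped by line, labelled sensitivity and time. For 4 of the 6 samples of 638bm VR the timepoint characteristic disagrees with title, description and source name, which give 1 time, and the times of the titles were used. Scanner files with slide numbers were not analysed here. Blocks of 6 consecutive columns of the table were treated as a candidate batch. The log2 background stood apart in the first block (5.44 to 5.54) and in the second (6.04 to 6.18). In the third and the fourth it overlapped (5.86 to 5.99 and 5.89 to 5.98), so that the boundary between these rests on column order alone. All 5 times of 595sp on their first arrays lay in 1 such block, together with untreated 595sp VR.

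Background was corrected with normexp (limma 3.58.1, R 4.3.3; saddle point method fitted on the probe signals, offset 16), followed by quantile normalization and log2. The offset makes fold changes of dim genes smaller than they are. A probe counted as above background on an array if its log2 signal exceeded the mode by 2.326 SDs of the values mirrored below the mode, which stands in for a detection p of 0.01. Probes above background on at least 2 arrays were kept, 21920 in all. Gene symbols came from the platform annotation given with the data: 34885 probes had 1 symbol, 18 had several and 10378 had none, and 34807 were found by gene number in a RefSeq gene table, with 0 symbols changed. Of the probes kept, 18241 had 1 symbol, for 11132 genes. The probe with the highest mean over all arrays stood for a gene, and 4590 genes had more than 1 probe kept.

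The 2 arrays of a line at 24 h were averaged, which left 20 values. Changes against 0 h, and their difference between arms, were tested with limma (lmFit and eBayes) in 1 model with cell line and sensitivity by time (8 residual and 7.72 prior degrees of freedom). All arms shared 1 estimate of the spread because each line has 1 untreated array. Untreated lines were compared in a model with origin (595sp or 638bm) and sensitivity by time (9 residual and 2.93 prior degrees of freedom). Most of these come from other times of the same lines, which are not independent replicates of the pairs. Errors and p-values of this model are therefore too small where the pairs disagree. Abcb1b, for example, differed by -4.231 in the 595sp and 0.442 in the 638bm pair, with an SE of 1.133. A gene was called in this model where the adjusted p was under 0.05 and both pairs differed by at least 1 log2 unit the same way. Elsewhere a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested). Errors are the standard errors of these fits. For a gene above background on no array of a group the fold was given as a bound, the bright group's mean against the lowest level above background in the dim group's arrays. Changes of single lines given for such genes run to or from a level not above background. The same cell line runs through all times of an arm, so the line pairs the samples. The difference between both lines correlated across genes between times at r = 0.771 to 0.907 in the sensitive and 0.822 to 0.925 in the resistant arm.

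Gene lists were fixed before the data were examined, 25 in all, and tested with camera (preset correlation 0.01), adjusted over 325 tests of 25 lists in 13 comparisons. Of these, 106 passed, and 0 passed with an estimated correlation. List members overlap in part, as with Sqstm1, Fas and Bbc3. Genes were named by a rule fixed before the data were examined. For the responses at 8 h and 24 h it took the 5 higher and 5 lower genes with the largest change in the line that changed less, among called genes moving the same way in both lines. For the difference of responses it took 5 in each direction by size, and for untreated lines 10 in each direction. It added up to 4 members with the smallest p per list, and always Psmb5, Myc and Bcl2l1. Genes of provisional name were left out.

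The tests were checked on simulated data with the real genes' means and spread. For the 24 h change in sensitive lines, 78% of 100 genes changed by 1 log2 unit and 100% of 100 changed by 2 were recovered, with 12 false calls. For the difference of the 24 h responses these shares were 32% and 98%, with 8 false calls, and for untreated lines 95% of 200 genes changed by 3 log2 units were recovered. Alternatives changed the background correction, the values used, the normalization, the filter, the probe rule, the treatment of the 24 h arrays, the model, the threshold, the times of 638bm VR and the lines included. Times were compared with 0 h without time-matched untreated arrays, so that time in culture and time in drug coincide. Probe positions in the genome were not used here.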

Results

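Gene expression was measured on 24 bead arrays, 6 for each of 4 mouse lines derived from multiple myeloma of animals that carry Bcl-XL and Myc transgenes. The lines 595sp and 638bm are labelled sensitive to bortezomib, a drug that inhibits the proteasome, and the lines 595sp VR and 638bm VR are labelled resistant. Each line was sampled before treatment and after 2, 8, 16 and 24 h in 33 nM bortezomib, with 1 array per time and 2 arrays at 24 h. The design asks how the lines respond over time, whether sensitive and resistant lines respond differently, and how they differ untreated. The 2 lines of an arm served as its replicates (n = 2 per arm and time). The labels do not say that the arrays came from separate cultures. With cell line in the model, p-values of the responses measure only how far changes differ between the 2 lines of an arm. This spread is pooled over times and arms. It holds neither the difference in level between lines nor the spread between cultures of a line. Between 15302 and 17679 of the 45281 probes stood above background on an array (33.8 to 39%). The number of arrays limits the precision. Both 24 h arrays of a line differed across genes by an SD of 0.18 to 0.26 on the log2 scale.

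The drug's target and the transgenes were read first. Psmb5, the proteasome subunit that bortezomib binds, was 1.12 ± 0.23 (log2 change ± SE, n = 2 lines) higher in the resistant lines at 8 h, with 0.58 in 595sp VR and 1.67 in 638bm VR (limma, adjusted p = 0.0124). In the sensitive lines its change was 0.55 ± 0.23 at 24 h and did not pass (adjusted p = 0.0925). These values are of unlike times and do not compare the arms. In the direct test of the difference 0 genes passed at 8 h, and no proteasome subunit passed at 24 h. Myc and Bcl2l1, the gene of Bcl-XL, passed at no time in either arm. Untreated Bcl2l1 averaged 14.90 on the log2 scale in the sensitive and 14.26 in the resistant lines, a difference of -0.63 ± 0.34 (adjusted p = 0.308). The files do not say whether these probes read the transgenes.

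After 8 h, chaperone genes showed the largest rises in the sensitive lines. Hspb1, a small heat shock protein, rose 18.8-fold (log2 4.24 ± 0.48, adjusted p = 0.000193). It stood above background on 1 of the 2 untreated arrays. Hsph1, a nucleotide exchange factor of the heat shock system, rose by 3.05 ± 0.36, and Hspa1a, an inducible 70 kDa chaperone, by 3.42 ± 0.57. Hspa1a too stood above background on 1 of the 2 untreated arrays. Impact, a regulator of translation, rose by 2.33 ± 0.25 and Zfand2a, a stress-inducible protein that binds the proteasome, by 2.24 ± 0.22. The largest falls by the same rule were in Ankrd37 (-3.17 ± 0.43), Gp6 (-2.21 ± 0.29), Aldoc, a glycolytic aldolase (-2.06 ± 0.23), Lbh (-2.11 ± 0.33) and Scd1, a fatty acid desaturase (-1.92 ± 0.28). The rule took only called genes that moved the same way in both lines, and the adjusted p of these 10 lay between 9.98e-05 and 0.00289. Other probes of Impact and Hspa1a read smaller changes. That of Impact changed by -0.006 in 595sp and 1.041 in 638bm, and those of Hspa1a by 3.588 and 0.413 and by 0.894 and 0.200. With the mean of a gene's probes the values were 1.421 for Impact and 1.988 for Hspa1a, and both passed.

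Of 31 measured proteasome subunits, 18 rose and 0 fell at 8 h in the sensitive lines, led by Psmd1 (1.46 ± 0.20), Psmd4 (1.25 ± 0.18), Psmc4 (1.21 ± 0.17) and Psmc2 (1.01 ± 0.16). The list passed camera (adjusted p = 1.32e-18), and its adjusted p was 0.249 with an estimated correlation. Adjusted over the list alone, 22 subunits rose. Of 21 heat shock proteins and co-chaperones, 11 rose, Chordc1 (1.77 ± 0.19) and Hspa8 (1.13 ± 0.17) among them, and 13 did so adjusted over the list alone. That list gave an adjusted p of 2.34e-12, and an adjusted p = 0.373 with an estimated correlation. Of 24 genes of the integrated stress response, 4 rose: Ddit3, a transcription factor linked to cell death (1.42 ± 0.26), Aars (1.04 ± 0.23), Slc7a11 (1.86 ± 0.42, with 3.246 in 595sp and 0.473 in 638bm) and Atf5 (1.05 ± 0.24). Adjusted over the list alone, 11 rose (camera adjusted p = 5.59e-07, and adjusted p = 0.562 with an estimated correlation). Of 20 chaperone and degradation genes of the endoplasmic reticulum, 3 rose: Hspa5 (0.84 ± 0.19), Creld2 (1.18 ± 0.29) and Pdia6 (1.11 ± 0.29, or 0.743 and not passing with the mean of its probes), and 7 did so adjusted over the list alone. Of 13 genes of sterol synthesis and uptake, 4 fell, with Dhcr7, the last enzyme of cholesterol synthesis, at -1.34 ± 0.21, and 7 fell adjusted over the list alone. In total 260 genes were higher and 332 lower than at 0 h, of 11132 tested (limma, adjusted p under 0.05). With median scaling in place of quantile normalization the split was 113 higher and 531 lower. With cell line left out of the model, 1 gene passed. In 595sp, whose first arrays all lay in 1 block of 6 table columns with a like background, the 8 h median was 0.87 for the proteasome and 1.51 for the heat shock list.

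**Figure D1:**
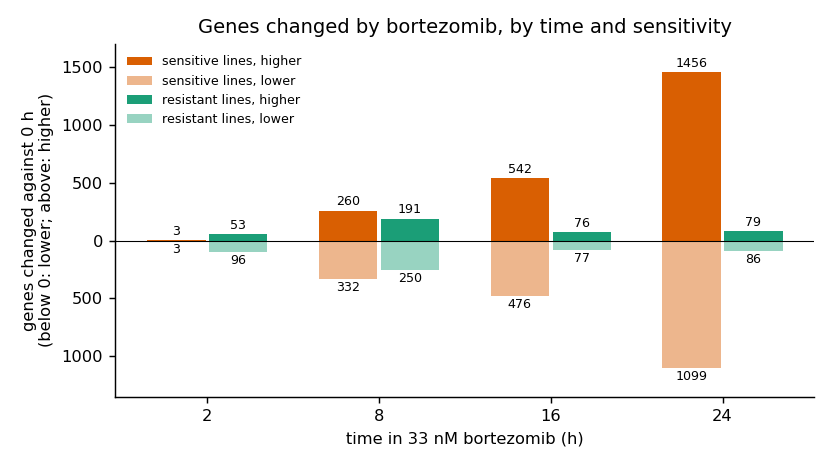
Number of genes higher (bars above 0) and lower (bars below 0) than at 0 h, against hours in 33 nM bortezomib, in the 2 sensitive and the 2 resistant lines. The sensitive lines reach 1456 higher and 1099 lower genes at 24 h, against 79 and 86 in the resistant lines.

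The sensitive lines changed little at 2 h, with 3 genes higher and 3 lower (3 and 1 with median scaling, 2 and 5 without background correction), and further at 16 h, with 542 higher and 476 lower. By 24 h, 1456 genes were higher and 1099 lower, and 800 of these changed at least 2-fold. Hspb1 then stood 33.6-fold above its untreated level (log2 5.07 ± 0.48, adjusted p = 1.27e-05) and Hspa1a at 4.66 ± 0.57, or 2.936 with the mean of its probes. Hspa1b was above background on 0 of the 2 untreated arrays and on 4 of 4 arrays at 24 h, and was at least 6.92-fold higher (adjusted p = 0.000834). Hspa1a and Hspa1b are near-identical copies, and their probes may not tell them apart. Sqstm1, a receptor of ubiquitin-tagged cargo in autophagy, rose by 2.45 ± 0.25 and Gabarapl1, an autophagosome protein, by 2.60 ± 0.19. Falls were led by Scd1 (-2.96 ± 0.28), Tfrc, the transferrin receptor (-2.86 ± 0.32), Cd93, a cell-surface glycoprotein (-3.07 ± 0.19), Scd2 (-2.68 ± 0.27) and Fcrla, a B-lineage gene (-2.46 ± 0.20).

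At 24 h in the sensitive lines, 26 of 31 proteasome subunits had risen (29 adjusted over the list alone), with Psmd4 at 1.72 ± 0.18, Psmc4 at 1.69 ± 0.17 and Psmd14 at 1.51 ± 0.17 (camera adjusted p = 7.73e-17, and adjusted p = 0.3 with an estimated correlation). Of the heat shock genes 13 of 21 had risen, and 14 adjusted over the list alone. In the integrated stress response list 11 of 24 rose, both at 16 h and at 24 h, with Ddit3 at 2.13 ± 0.26, Atf5 at 1.64 ± 0.24 and Atf4 at 1.25 ± 0.21 at 24 h. Oxidative stress and metal response genes rose in 7 of 15 cases, with Gclm, a subunit of the enzyme of glutathione synthesis, at 1.84 ± 0.28 and Ftl1, a ferritin chain, at 1.45 ± 0.26 (camera adjusted p = 0.00589, and adjusted p = 0.575 with an estimated correlation). Autophagy and ubiquitin-binding genes rose in 7 of 18 cases, Tax1bp1 by 1.53 ± 0.19 and Atg12 by 1.03 ± 0.17. At 8 h 4 of these 18 had risen, and the list's median at 8 h turned from 0.14 to just below 0 with median scaling.

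Of 13 genes of MHC class II and antigen presentation, 10 fell in the sensitive lines at 24 h, over all genes and adjusted over the list alone. H2-DMa fell by 1.89 ± 0.18, H2-Eb1 by 1.68 ± 0.16 and H2-Ab1 by 1.79 ± 0.18 (camera adjusted p = 3.33e-09, and adjusted p = 0.183 with an estimated correlation). At 16 h 7 of the 13 were lower. In the sterol list 8 of 13 fell, Cyp51, lanosterol demethylase, by 2.86 ± 0.40, Sqle, squalene epoxidase, by 2.22 ± 0.40, Dhcr7 by 2.08 ± 0.21 and Srebf2, the transcription factor of this pathway, by 1.98 ± 0.26 (camera adjusted p = 5.52e-06, and adjusted p = 0.501 with an estimated correlation). Of 13 plasma cell genes 5 fell, with Slamf7 at -1.502 ± 0.214, Fkbp11 at -1.26 ± 0.23 and Sdc1, which encodes syndecan-1, at -1.07 ± 0.24, and 1 rose (camera adjusted p = 0.00246, and adjusted p = 0.231 with an estimated correlation). The endoplasmic reticulum list, with 3 members up at 8 h, had 2 up and 4 down at 24 h, Syvn1 at -1.40 ± 0.24 and P4hb at -1.20 ± 0.23 against Xbp1 at 0.87 ± 0.21. Among 17 BCL-2 family and death receptor genes 5 rose and 1 fell, and among 13 p53 targets 4 rose. Bbc3 (0.90 ± 0.23) and Fas, both in the 2 lists, were among them. Fas was above background on 0 of 2 untreated arrays and on 4 of 4 arrays at 24 h, and was at least 1.79-fold higher as a mean of both lines (adjusted p = 0.0041). Its change, taken from a level not above background, was 0.605 in 595sp and 2.019 in 638bm. Neither list passed camera (adjusted p = 0.232 and 0.228). With cell line left out of the model, 150 genes passed at 24 h, 63 higher and 87 lower, and 2 passed at 16 h. Median scaling gave 280 higher and 556 lower at 16 h.

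**Figure D2:**
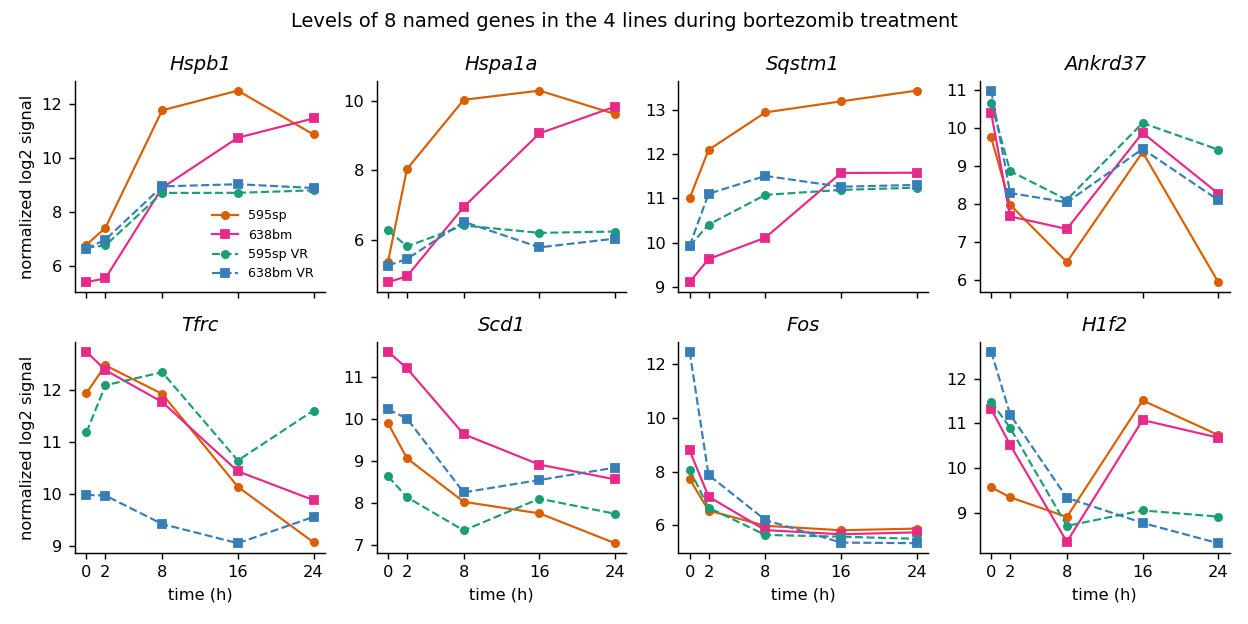
Normalized log2 signal of 8 named genes against hours in bortezomib, 1 line per cell line (solid for sensitive, dashed for resistant), with 1 array per point and the mean of 2 arrays at 24 h. Hspb1 rose by 5.07 in the sensitive and by 2.19 in the resistant lines at 24 h, and Fos fell by 7.15 in 638bm VR and by 2.58 in 595sp VR.

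In the resistant lines at 8 h, Hspb1 rose by 2.17 ± 0.48 (adjusted p = 0.0193), Impact by 2.11 ± 0.25 (its other probe by 0.377 in 595sp VR and 1.513 in 638bm VR) and Hsph1 by 1.54 ± 0.36. Trafd1, a zinc finger protein of innate immune signalling, rose by 2.21 ± 0.17 (adjusted p = 6.42e-06) and Glipr1 by 2.11 ± 0.30. Falls were led by H1f2, a linker histone (-3.02 ± 0.46), Ankrd37 (-2.74 ± 0.43), Ndrg1 (-2.66 ± 0.39), Aldoc (-2.12 ± 0.23) and Fos, a subunit of the transcription factor AP-1 (-4.36 ± 0.72). The log2 change of Fos was -2.44 in 595sp VR and -6.28 in 638bm VR. Of the 31 proteasome subunits 23 rose (28 adjusted over the list alone), Psmd6 by 1.52 ± 0.21 and Psmd1 by 1.43 ± 0.20 (camera adjusted p = 1.36e-27, and adjusted p = 0.183 with an estimated correlation). Heat shock genes rose in 7 of 21 cases, Cacybp by 1.16 ± 0.20 among them (camera adjusted p = 7.67e-07, and adjusted p = 0.562 with an estimated correlation). In the endoplasmic reticulum list 4 of 20 rose, Hspa5 by 1.06 ± 0.19 and Creld2 by 1.33 ± 0.29. Hspa5 stood above background on 1 of the 2 untreated resistant arrays, with a mean log2 level of 5.520. Oxidative stress genes rose in 6 of 15 cases, Gclm by 1.55 ± 0.28, and autophagy genes in 4 of 18, Vcp by 1.13 ± 0.20. Txnrd1, a thioredoxin reductase of the oxidative stress list, was above background on 0 of 2 untreated resistant arrays and at least 1.91-fold higher at 8 h (adjusted p = 0.0147). Aars was the 1 gene of the integrated stress response list that rose (1.13 ± 0.23, or 0.609 and not passing with the mean of its probes), and Stc2 fell (-1.73 ± 0.34). Of 19 immediate early genes 5 fell, with Dusp1, a phosphatase of MAP kinases, at -3.24 ± 0.64, from -1.399 in 595sp VR and -5.08 in 638bm VR (camera adjusted p = 0.00145, and adjusted p = 0.575 with an estimated correlation). Fosb, another AP-1 subunit, was above background on 2 of 2 untreated arrays and on 0 of 2 at 8 h, and was at least 9.18-fold lower as a mean of both lines (adjusted p = 0.024). Its change, taken to a level not above background, was -1.154 in 595sp VR and -5.349 in 638bm VR, and it passed in 12 of 18 settings. Dusp1 was at -4.229 in 638bm VR at 2 h already, and all changes of a line run from its 1 untreated array. That array differed from untreated 638bm by 2.005 for Jund, 1.877 for Klf4 and -0.625 for Ier2 of this list. A high level on that array cannot be told apart from a fall under drug. Of the MHC class II list 5 of 13 fell, H2-Eb1 by 0.85 ± 0.16 and Ciita, its transcriptional activator, by 0.78 ± 0.19, or -0.445 and not passing with the mean of its probes.

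In total the resistant lines had 53 genes higher and 96 lower at 2 h (124 and 67 with median scaling), and 191 higher and 250 lower at 8 h. Of the genes called at 8 h, 78 were higher in both arms, against 4.5 for independent lists of those sizes, and 107 were lower in both, against 7.5. The log2 changes of both arms correlated across genes at 8 h (r = 0.603), where genes are not independent replicates and the arms share no array. These counts rest on both resistant lines, and they fell furthest without 638bm VR. Without it, the resistant arm had 0 genes at 2 h, 2 at 8 h, 0 at 16 h and 0 at 24 h. Without 595sp VR the counts at those times were 30, 64, 33 and 29, and with cell line left out of the model they were 0 throughout.

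At 24 h the resistant lines had 79 genes higher and 86 lower, and at 16 h 76 higher and 77 lower. Median scaling gave 238 higher and 76 lower at 24 h, and 218 higher and 53 lower at 16 h. Hspb1 remained higher by 2.19 ± 0.48 (passing in 10 of 18 settings, and in 12 at 8 h), Trafd1 by 2.12 ± 0.17 and Glipr1 by 1.83 ± 0.30. Mlkl, the pseudokinase of necroptosis, rose by 2.55 ± 0.31 and Casp1, an inflammatory caspase, by 1.37 ± 0.18. Fos fell by 4.86 ± 0.72 and stood above background on 1 of 4 arrays at 24 h, and its untreated log2 level was 12.48 in 638bm VR against 7.73 to 8.79 in the other lines. H1f2 (-3.43 ± 0.46), Dusp1 (-3.265 ± 0.643, with -1.556 in 595sp VR and -4.974 in 638bm VR), the histone gene H2ac19 (-1.73 ± 0.26) and Tgfb3 (-1.497 ± 0.278) fell too. Of the proteasome subunits 14 of 31 were higher (27 adjusted over the list alone; camera adjusted p = 1.71e-28, and adjusted p = 0.183 with an estimated correlation), with Psmc4 at 1.19 ± 0.17 and Psmd1 at 1.31 ± 0.20. Heat shock genes were higher in 2 of 21 cases and autophagy genes in 3 of 18, with Gabarapl1 at 1.11 ± 0.19. Immediate early genes fell in 5 of 19 cases, in 638bm VR from the same untreated array as at 8 h. MHC class II genes fell in 5 of 13 cases, H2-Eb1 by 1.18 ± 0.16 and Cd74, the invariant chain, by 0.83 ± 0.17 (camera adjusted p = 1.36e-05, and adjusted p = 0.19 with an estimated correlation). No sterol gene passed, with Dhcr7 at -0.19 ± 0.21. DNA replication genes passed camera as higher (adjusted p = 2.05e-05, and adjusted p = 0.665 with an estimated correlation). Their median was 0.76 in 638bm VR and 0.01 in 595sp VR, and 1 of 25 passed by itself. For 4 samples of 638bm VR the time in the labels' characteristic disagrees with the title, and with the characteristic's times 1 gene passed at 24 h and 40 at 16 h. With the 16 h and 24 h arrays of 638bm VR left out, 1 gene passed at each of those times.

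**Figure D3:**
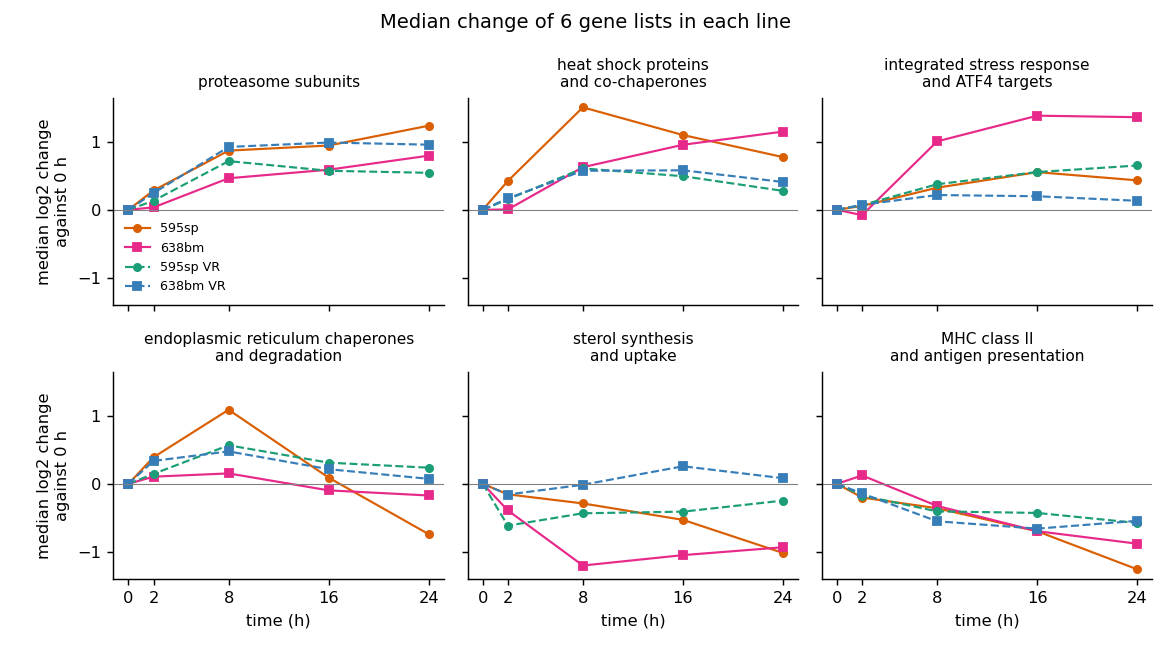
Median log2 change against 0 h of the measured members of 6 gene lists, in each of the 4 lines (solid for sensitive, dashed for resistant), against hours in bortezomib. At 24 h the median of the 31 proteasome subunits was 1.24 in 595sp, 0.80 in 638bm, 0.54 in 595sp VR and 0.96 in 638bm VR.

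The responses were then compared directly, as the resistant change minus the sensitive change. At 24 h, 105 genes had a more positive change in the resistant lines and 33 a more negative one. Cyp51 differed by 2.92 ± 0.56 (adjusted p = 0.0232), Tfrc by 2.86 ± 0.45, Psg23, a pregnancy-specific glycoprotein, by 2.37 ± 0.42, Mogs, a glucosidase of N-glycan trimming, by 2.21 ± 0.28 (adjusted p = 0.00871) and Scd2 by 2.19 ± 0.38. On the other side stood Hspa1a (-4.29 ± 0.80, or -2.819 with the mean of its probes), H1f2 (-3.69 ± 0.66), Hspb1 (-2.89 ± 0.67, adjusted p = 0.049) and the histone genes H2bc7 (-2.11 ± 0.46) and H2bc6 (-2.05 ± 0.47). Of 18 settings of the analysis, Hspb1 passed in 8 (-3.387 to -2.442, adjusted p up to 1), H2bc6 in 11 and H2bc7 in 14. The runs without 1 line are not among these 18. Another probe of H2bc6 differed by -0.525 and -1.145 in the 595sp and 638bm pairs. Of the sterol list 3 of 13 had a more positive change in the resistant lines (7 adjusted over the list alone), Dhcr7 by 1.89 ± 0.29, Cyp51 and Srebf2 by 1.77 ± 0.37 (camera adjusted p = 6.77e-07, and adjusted p = 0.454 with an estimated correlation). Cyp51 and Srebf2 were also lower in untreated resistant lines (-2.794 and -1.527), as was Psg23. Both comparisons rest on the same untreated arrays. In the sensitive lines Cyp51 fell from a mean log2 level of 11.615 to 8.753 at 24 h, near the untreated resistant mean of 8.820. Dhcr7 too started lower in the resistant lines, at 7.175 against 8.815, and stood at 6.738 in the sensitive lines at 24 h. For these genes a differing response cannot be told apart from unlike starting levels. In the integrated stress response list Ddit3 (-1.66 ± 0.36) and Ppp1r15a (-1.90 ± 0.35, with -1.03 and -2.772 in the 595sp and 638bm pairs) had a more negative change, as did Gabarapl1 (-1.48 ± 0.26) in the autophagy list. Ppp1r15a and Gabarapl1 started higher in the resistant lines (9.044 against 8.153, and 8.817 against 7.722), though neither passed untreated. The limit of unlike starting levels holds for both. No proteasome subunit passed this test: Psmd4, the one with the smallest p, was at -0.81 ± 0.25 (adjusted p = 0.115). The list gave an adjusted p of 0.0225 as a set, and an adjusted p = 0.802 with an estimated correlation. Its median difference was -0.68 between 595sp VR and 595sp and 0.17 between the 638bm lines. No MHC class II gene passed over all genes, and 6 of 13 did adjusted over the list alone, all toward a smaller fall in the resistant lines. H2-DMa and Tapbp of this list started lower in the resistant lines (8.650 against 10.218, and 7.433 against 8.553). A smaller fall thus cannot be told apart from unlike starting levels here either. At 2, 8 and 16 h limma called 0 genes, with 317, 774 and 1203 at an unadjusted p under 0.05. The 24 h count was 0 without 638bm VR, 4 without 595sp VR and 0 with cell line left out of the model. Median scaling gave 208 more positive and 20 more negative, and 24 separate arrays with the blocks of 6 table columns as a term gave 302 and 191. The split was 132 and 95 without background correction and 139 and 89 on the authors' processed values.

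Untreated resistant and sensitive lines differed in 293 genes, 50 higher and 243 lower in the resistant lines, in both pairs by at least 1 log2 unit, a rule set before the data were seen. At the adjusted p alone 258 were higher and 376 lower, in a model whose errors are too small where the pairs disagree. Ifitm1, an interferon-induced membrane protein, was 18.3-fold higher (log2 4.20 ± 0.35, adjusted p = 0.000618), by 3.70 in the 595sp pair and 4.70 in the 638bm pair. Cbs, cystathionine beta-synthase, was higher by 1.94 ± 0.28, Fzd6, a Wnt receptor, by 1.91 ± 0.28, Tst by 2.20 ± 0.56 and Thop1, a peptidase, by 1.501 ± 0.292. The protocadherins Pcdhgb4 and Pcdhgc5 were higher by 1.72 ± 0.34 and 1.65 ± 0.37, and Gid4, Cerox1 and Zfp763 by 1.38 to 1.55. Pex13, a peroxisome import protein, was above background on 0 of 2 untreated resistant arrays and at least 6.72-fold lower. Nktr (-3.02 ± 0.36), Tmem164 (-2.87 ± 0.38), Psg23 (-2.76 ± 0.57), Cyp51 (-2.79 ± 0.65) and the importin Ipo7 (-2.55 ± 0.48) were lower too, as were Slc38a2, an amino acid transporter (-2.49 ± 0.33), Hadha (-2.53 ± 0.43), the channel Trpm7 (-2.52 ± 0.44) and Tspoap1 (-2.55 ± 0.51). Other probes of some of these genes did not follow. The other probe of Pex13 differed by -0.02 and 0.17 in the 595sp and 638bm pairs, and that of Tmem164 by 0.09 and -0.18. Slc38a2 had 1 other probe at 0.50 and 0.21 and another at -1.35 and -1.83, and 1 of Ifitm1 stood at 0.51 and 2.83. With the mean of its probes Gid4 was at 0.802, under the least difference for a call.

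**Figure D4:**
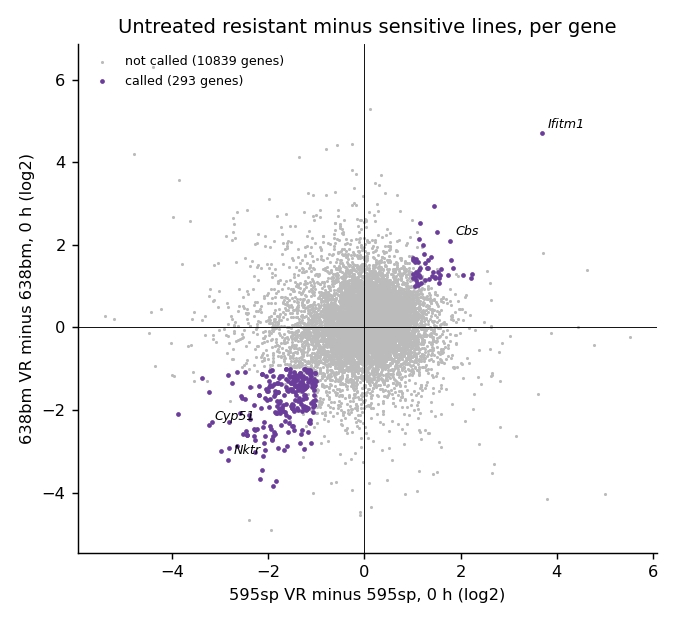
Log2 difference of each gene between the untreated resistant and sensitive line, for the 638bm pair against the 595sp pair, 1 array per line. The 293 called genes lie in the quadrants where both pairs differ the same way by at least 1, and 243 of them are lower in the resistant lines.

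MHC class II and antigen presentation genes were lower in untreated resistant lines in 5 of 13 cases, and in 12 adjusted over the list alone, with H2-DMa at -1.57 ± 0.25, H2-DMb1 at -1.44 ± 0.23 and Tapbp, tapasin, at -1.12 ± 0.20, or -0.13 and not passing with the mean of its probes (camera adjusted p = 2.46e-11, and adjusted p = 0.231 with an estimated correlation). Sterol genes were lower in 4 of 13 cases: Msmo1 (-2.32 ± 0.43), Cyp51, Sqle (-1.94 ± 0.47) and Srebf2 (-1.53 ± 0.29), with a camera adjusted p of 0.00195, and adjusted p = 0.562 with an estimated correlation. The endoplasmic reticulum list had 1 gene lower, Syvn1 (-1.46 ± 0.29). Of 15 interferon-stimulated genes 0 passed and 3 did adjusted over the list alone, all lower (camera adjusted p = 0.00032, and adjusted p = 0.545 with an estimated correlation). Of 4 drug efflux transporters 0 passed and 1 did adjusted over the list alone, Abcc1, which was above background on 0 of 2 untreated resistant arrays and at least 1.61-fold lower there (camera adjusted p = 0.0165 for the list, and adjusted p = 0.423 with an estimated correlation). Among markers of other cells 2 were lower in untreated resistant lines, the T cell marker Zap70 (-2.22 ± 0.31, or -1.449 with the mean of its probes) and the myeloid marker Fcgr3 (-2.11 ± 0.49), each above background on 1 of 2 resistant arrays. Neither marker list passed (adjusted p = 0.386 and 0.248). No proteasome subunit met the least difference of 1 log2 unit in both pairs. At the adjusted p alone Psmd7 and Psmd11 passed: Psmd7 (0.69 ± 0.16, adjusted p = 0.0282), higher by 0.889 in the 595sp and 0.491 in the 638bm pair, and Psmd11 (0.745 ± 0.194, adjusted p = 0.0459), by 0.984 and 0.506. The untreated differences of both pairs correlated weakly across genes (r = 0.109): 360 genes differed by at least 1 log2 unit the same way in both and 200 in opposite ways. In all, 1738 genes differed by that much in the 595sp pair and 1857 in the 638bm pair. Unrelated pairs would thus share some genes as well, a number not computed here. The pairs rest on the names of the lines. Kdm5d, a Y-linked gene chosen after its values were seen, was above background on 6 of 6 arrays of 595sp and on 0 of 6 of 595sp VR. The count was 118 with origin left out of the model, and with 1 of the 4 lines left out, where only 1 pair remained to meet the rule, it was 1335 to 1789.

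Mitosis genes passed camera as lower at 8 h in both arms (adjusted p = 0.00327 in the sensitive and 0.00211 in the resistant lines, and adjusted p = 0.698 and 0.696 with an estimated correlation), with 0 and 2 of 16 lower by themselves, Cenpa at -0.76 ± 0.17 and Nusap1 at -1.22 ± 0.29 in the resistant lines. Ribosome biogenesis and MYC targets had 1 of 20 higher at 8 h in each arm (camera adjusted p = 0.00418 and 0.00197, and adjusted p = 0.742 and 0.7 with an estimated correlation). Of 5 genes of the immunoproteasome and its activator 2 fell in the sensitive lines at 8 h (camera adjusted p = 0.0205, and adjusted p = 0.575 with an estimated correlation). Of 14 NF-kB targets 3 rose and 1 fell in the sensitive lines at 24 h. Relb rose by 1.35 ± 0.29 and Icam1 fell by 0.90 ± 0.25, and the list did not pass. Among mature B cell genes 4 of 14 fell at 24 h in the sensitive lines, Cd22 by 2.21 ± 0.33, Cd79b by 1.32 ± 0.27 and Cd37 by 1.10 ± 0.16 among them, and Bcl6 rose by 1.02 ± 0.20 (camera adjusted p = 0.0958). Of the 4 drug efflux transporters, Abcc5 was higher in the sensitive lines by 1.998 ± 0.239 at 8 h (camera adjusted p = 0.0292 for the list, and adjusted p = 0.575 with an estimated correlation). At 24 h Abcc5 was higher there by 0.955 ± 0.239 (0.519 and not passing with the mean of its probes), while Abcc4 fell by 1.11 ± 0.21 and Abcb1b changed by -1.32 ± 0.39, with -2.55 in 595sp and -0.10 in 638bm. In the resistant lines none of the 4 passed at 2, 8, 16 or 24 h, and Abcc4 had a more positive change there than in the sensitive lines at 24 h (1.31 ± 0.30, adjusted p = 0.0468). Of 9 genes listed as T cell markers, 2 fell at 8 h in the sensitive lines, Zap70 (-0.78 ± 0.19) and Cd2 (-1.29 ± 0.36), with a camera adjusted p of 0.0466, and adjusted p = 0.454 with an estimated correlation. Untreated Cd2 stood above background on 2 of 2 arrays of the sensitive lines, at a mean log2 level of 9.222. Whether these transcripts came from other cells was not tested. Cd2 was also lower there at 24 h (-1.44 ± 0.36), and at 2 h in the resistant lines it changed by 1.60 ± 0.36 (adjusted p = 0.042). Across 18 settings that value ran from 0.453 to 1.779 and passed in 8, and the fall of Cd2 at 8 h passed in 8 too. No myeloid (6 measured), erythroid (4) or stromal (2) marker passed in a response at 2, 8, 16 or 24 h, and those lists did not pass. Of 9 housekeeping genes 1 fell in the sensitive lines at each of 8, 16 and 24 h. It was Gapdh at 8 h (-0.56 ± 0.16, adjusted p = 0.0471) and Gusb, a lysosomal glucuronidase, at 16 h (-1.56 ± 0.20) and 24 h (-2.30 ± 0.20, adjusted p = 9.29e-06). The change of Gusb was more positive in the resistant lines at 24 h (1.61 ± 0.29, adjusted p = 0.0191). The list passed in none of the 13 comparisons (adjusted p = 0.208 at 8 h and 0.656 at 24 h in the sensitive lines).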

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

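The tests of a batch of arrays and of the time characteristic in this part were stated before their results were seen. The other tests were chosen after the pattern was seen.

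Changes from 0 h to 24 h differed between the arms in 138 genes by the test of the difference itself (resistant minus sensitive change, limma, both pairs the same way). Without time-matched untreated arrays these are not differences of the drug's effect alone. The largest were Cyp51 (2.921), Tfrc (2.855), Psg23 (2.365), Mogs (2.212) and Scd2 (2.185) on the positive side, and Hspa1a (-4.287), H1f2 (-3.693), Hspb1 (-2.887), H2bc7 (-2.106) and H2bc6 (-2.048) on the negative side. Cyp51 and Psg23 were also lower in untreated resistant lines, and both comparisons share the untreated arrays. Hspb1 passed in 8 of 18 settings of the analysis, H2bc6 in 11 and H2bc7 in 14, with the runs without 1 line not counted. Among the gene lists, the difference passed camera with a preset correlation for 4 lists at 8 h, 7 at 16 h and 10 at 24 h, and for 0 with an estimated correlation. In data outside the gene comparisons, 578 of 3679 probes with no gene name changed in the sensitive lines at 24 h, 210 higher and 368 lower. Between untreated resistant and sensitive lines 245 such probes differed, 14 higher and 231 lower. One array was flagged: the background of the first 24 h array of 595sp was 5.443 on the log2 scale, against 5.89 to 5.982 on the other sensitive arrays at 24 h. That array lay in the first block of 6 table columns, where all backgrounds were 5.44 to 5.54, and the others lay in later blocks. It thus did not stand apart from its block. The flag was 1 among 110 groups of 4 arrays checked, where chance gives 5.5.

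The sensitive lines had 2555 genes changed at 24 h and the resistant lines 165. A batch of arrays does not account for this by itself, since within 1 block of 6 consecutive table columns the 24 h change of 595sp had an SD across genes of 0.654, above the larger resistant SD of 0.438. Wrong times of 638bm VR leave 595sp VR untouched, and its SD of 0.36 lay below 0.598, the smaller sensitive value. Fewer probes above background on treated sensitive arrays would need a fall in both sensitive lines, but the share rose by 0.35 percentage points in 638bm and changed by -2.26 in 595sp VR. The labelled difference in sensitivity remains as a hypothesis, and the share of dying cells at 24 h was not tested.

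Of the 243 genes lower in untreated resistant lines by at least 1 log2 unit in both pairs (376 lower and 258 higher at the adjusted p alone), 170 also fell in treated sensitive lines at 24 h (24 expected for independent lists), with a median log2 change of -1.007. Both comparisons share the untreated sensitive arrays, which with no effect gave a median of -0.274 in 20 simulations. In lines that share no array with the choice of genes, the median 24 h change was -0.233 in 638bm (1062 genes lower in the 595sp pair) and -0.538 in 595sp (918 genes lower in the 638bm pair), which argues against shared arrays as the whole cause. Other probes of these genes were lower too, by a median of -0.618 untreated and -0.347 at 24 h over 139 genes, which argues against single misleading probes as the whole cause, though their median ratio to the main probe was 0.383 against 0.591 for genes lower in sensitive lines at 24 h. Transcripts that the annotation does not name may contribute and stay open: probes with no gene name were lower in untreated resistant lines in 6.14% of cases (226, with named and unnamed probes adjusted together, against 231 adjusted alone) and named ones in 2.82% (odds ratio 2.26, 95% interval 1.91 to 2.66, Fisher's exact test), and a biological cause tied to resistance was not tested.

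For 4 samples of 638bm VR the time characteristic disagrees with the title. Their changes correlated with those of 595sp VR across genes at a mean r of 0.438 at the time of the title and 0.347 at that of the characteristic, and the title's time was higher in 3 of the 4, with the 16 h sample as exception (0.392 against 0.454). This argues against the characteristic as the right time. An exchange of the names of both resistant lines is argued against by 46 genes above background on all arrays of both lines with a shared name and on none of the others, against 6 for the crossed pairs. Of the 46, 36 were of the 595sp lines and 10 of the 638bm lines. A wrong time of the 16 h sample alone stays open.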

How the results depend on the processing

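The blocks of 6 arrays, the offset of 50, the omission of 638bm VR at 16 h and 24 h, and fry were chosen after seeing the data; the other alternatives were set before. No called change of a named gene turned direction under any setting run. Among changes that were not called, those of Psmb5, Myc and Bcl2l1 crossed 0 in part, as for Myc from -0.243 to 0.127 at 8 h in the sensitive lines. Of 1510 values of genes named by the rule, 1323 kept their side of the threshold and 187 lost the call. Of 3733 values of further called list members, 2966 kept the call and 767 lost it, the latter in 164 of 177 changes. Among 106 list tests that passed, 2 turned direction under 3 other scalings, both times the autophagy list with median scaling (at 8 h in the sensitive lines from 0.137 to -0.002, and for the difference at 16 h from -0.219 to 0.049). Median scaling moved the median of all genes by more than 0.1 in 6 comparisons: -0.101 at 8 h in the sensitive lines, 0.111 and 0.101 at 16 h and 24 h in the resistant lines, and 0.12, 0.137 and 0.151 for the difference at 2, 8 and 16 h. Where signal over background is low, as for Hspa1b and Pex13, only a bound can be given. A slide block was not run, since the files used name no slide. Camera was not run for the random block, trend and robust, or the fold threshold. Unless said otherwise, the cause of a shift was not tested.

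Counts that moved by over 1.5 times follow. Without background correction the 24 h difference had 227 genes and untreated lines 176. The authors' processed values gave 228 for the 24 h difference. Median scaling gave 271 and 314 for the resistant lines at 16 h and 24 h, and 14 and 228 for the difference at 16 h and 24 h. Without a filter the 16 h difference had 2 genes. Mean probes per gene gave 3 at 2 h in the sensitive lines and 89 for the 24 h difference. Treating all 24 arrays as separate values, which counts both 24 h arrays of a line as replicates, gave 18 and 923 in the sensitive lines at 2 h and 8 h, 316, 665, 293 and 709 in the resistant lines at 2, 8, 16 and 24 h, and 31 and 990 for the difference at 16 h and 24 h. Line and time as a random block gave 12 at 2 h in the sensitive lines, 262 at 24 h in the resistant lines, and 9 and 347 for the difference at 16 h and 24 h. The blocks of 6 arrays as a term gave 18 at 2 h in the sensitive lines, 224 and 706 at 2 h and 8 h in the resistant lines, and 1 and 493 for the difference at 16 h and 24 h. Trend and robust gave 1 for the 16 h difference. An added threshold of 1 log2 unit, which can only lower counts, left 219, 312 and 800 in the sensitive lines at 8, 16 and 24 h, and 72, 185, 73 and 97 in the resistant lines. An offset of 50 gave 219 for the 24 h difference and 189 for untreated lines. Camera, which compares a list with the other genes, passed 106 list tests with a preset and 0 with an estimated correlation. Fry asks another question, whether a list's genes move on balance one way, and passed 36, so the counts of both tests are not of 1 kind.

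The lines pair the samples, and without the replicate block (cell line or origin left out) the differences between lines enter the spread. The sensitive lines then had 0, 1, 2 and 150 genes at 2, 8, 16 and 24 h, the resistant lines 0 at each time, the 24 h difference 0 and untreated lines 118, and 16 of 70 named genes passed. With the characteristic's times for 638bm VR, the resistant lines had 182, 40 and 1 genes at 8, 16 and 24 h, the sensitive lines 0 at 2 h and the 24 h difference 66. With 638bm VR at 16 h and 24 h left out, the resistant lines had 50, 263, 1 and 1, the sensitive lines 354 at 8 h and the 24 h difference 0; fewer samples entered that fit.

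Leaving out 1 of the 4 lines left an arm with 1 line, which is assumed to vary like the other arm. The sensitive counts then ranged from 2 to 26 at 2 h, 159 to 714 at 8 h, 307 to 940 at 16 h and 1525 to 2512 at 24 h. The resistant counts ranged from 0 to 376 at 2 h, 2 to 917 at 8 h, 0 to 334 at 16 h and 0 to 327 at 24 h, lowest without 638bm VR in each case. The difference ranged from 0 to 6 at 2 h, 0 to 8 at 8 h, 0 to 33 at 16 h and 0 to 834 at 24 h, untreated lines from 1335 to 1789, and named genes passing from 42 to 70.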

Other observations

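The tests of the list of hypoxia-inducible genes and of histone genes were stated before their results were seen, though the lists were prompted by named genes. The test of the transporter class was chosen after the result was seen.

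Genes induced by low oxygen fell in both arms at 8 h. Of 30 measured members of the added list, 13 fell in the sensitive and 14 in the resistant lines, and 0 rose in either. Of the 27 that did not prompt the list, 11 fell in each arm. Beside Ankrd37, Aldoc and Ndrg1, which prompted the list, Pdk1, a kinase that restrains pyruvate dehydrogenase, fell by 1.70 ± 0.21 in the sensitive and 1.44 ± 0.21 in the resistant lines. Bnip3l, a mitophagy receptor, fell by 1.57 ± 0.20 and 1.67 ± 0.20, and Slc16a3, a lactate exporter, by 1.56 ± 0.18 and 0.76 ± 0.18. Ldha fell by 1.26 ± 0.18 and 0.74 ± 0.18, Tpi1 changed by -1.199 ± 0.176 and -1.304 ± 0.176, and Vegfa fell by 1.54 ± 0.35 in the resistant lines. Over the 27 members that did not prompt the test, the line medians at 8 h lay between -0.983 and -0.67, below 0 in each of the 4 lines and under 3 other scalings. These 27 members, without the prompting genes, passed camera in both arms at 8 h (adjusted p = 4.76e-12 in the sensitive and 5.65e-16 in the resistant lines over 20 tests), and with an estimated correlation too (adjusted p = 0.0464 and 0.0437). The unadjusted camera p with an estimated correlation was 0.0101 and 0.00437. The fixed lists were adjusted over 325 tests, so these adjusted values cannot be set against theirs. The list was lower at 2 h already, with a median of -0.421 in the sensitive and -0.646 in the resistant lines (adjusted p = 0.0464 in both with an estimated correlation). At 16 h the median was -0.001 in the sensitive (adjusted p = 0.871 with an estimated correlation) and -0.436 in the resistant lines (0.0951), and at 24 h -0.663 (0.0951) and -0.698 (0.0437). A common fall of genes under hypoxia-inducible factor is a candidate explanation. A change of medium or of cell density at the start of treatment may act in the same direction and from 2 h on, and no untreated array at later times exists in the data used to tell it from the drug.

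Histone genes were among the largest falls of the resistant lines. Of 53 measured, 4 were named by the rule and prompted the list (H1f2, H2ac19, H2bc6 and H2bc7). Of the 49 others, 12 fell in the resistant lines at 24 h and 1 in the sensitive lines, and 2 differed between the responses. H2bc4 fell by 2.03 ± 0.38, H2bc9 by 1.82 ± 0.31 and H4c9 by 1.36 ± 0.25. Histone genes of 1 type are near copies, so their probes are not independent. Over these 49 members the median at 24 h was -0.412 in 638bm VR and -0.087 in 595sp VR, the latter within its bootstrap SE of 0.18. Whether the family may fall as a whole cannot be told apart from a fall of some members, since 28 of 49 were below 0 in 595sp VR.

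Genes with Slc, Slco, Tmem, Tm9sf or Tspan symbols, many of them transporters or transmembrane proteins, made up 26 of the 243 genes lower in untreated resistant lines and 383 of 11132 tested. The class was chosen from these 243 genes, so this share is no test of it. With the 243 genes left out, the median untreated difference of the other 357 members lay below that of other genes in the 595sp pair (-0.139 ± 0.033, bootstrap SE, against 0.102) and in the 638bm pair (-0.013 ± 0.039 against 0.092). Under 3 other scalings it lay below in both pairs too, by differences of -0.26 to -0.06. A small shift of the class relative to other genes is a candidate explanation (-0.105 in the pair where it was smaller), and its cause was not tested. Among the other genes that fell in treated sensitive lines at 24 h, 64 of 929 were of the class (odds ratio 2.44, 95% interval 1.82 to 3.24), a comparison that shares the untreated sensitive arrays and is not independent. In the resistant lines 0 of 86 genes lower at 24 h were of the class, against 3.44% of all genes tested, a difference that did not pass Fisher's exact test (adjusted p = 0.145, odds ratio interval 0 to 1.23).

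Kdm5d, a Y-linked gene chosen after its values were seen, was above background on 6 of 6 arrays of 595sp (log2 6.30 ± 0.32, SD over arrays) and on 0 of 6 arrays of each other line, with 4.64 ± 0.27 in 595sp VR. The untreated comparison pairs 595sp VR with 595sp by name, and this value puts in doubt, without deciding, that both lines share an origin. Against that stand 36 genes above background on all arrays of both 595sp lines and on none of the 638bm lines.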
